A study of Mus musculus with 31 samples.

How the data were processed

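Poly(A) RNA from neocortex of wild-type (WT) mice and of mice labelled as a conditional knockout (cKO) of HuR, the RNA-binding protein encoded by Elavl1, was sequenced at embryonic day 13 (E13) and on the day of birth (P0). At each age, RNA came from total lysate and from 2 pools of a sucrose gradient that had been collected as 14 fractions. Fractions 4 to 7, which the labels assign to ribosomal subunits and single ribosomes, formed the monosome pool, and fractions 9 to 12 formed the polysome pool. Per the labels, the authors prepared TruSeq libraries, sequenced both ends over 100 bases, and used TopHat2 2.0.6, Bowtie2 2.0.5.0 and Cuffdiff with the mouse builds mm10 and GRCm38. The version of Cuffdiff, the gene annotation and the scaling between libraries are not given in the sources used here.

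The deposited values are FPKM (fragments normalized to transcript length and library size), with a column per library, in one table for the 15 WT libraries and another for the 16 libraries labelled cKO. The median log2 ratio between libraries varied over a range of 0.598 in the WT table and 0.088 in the cKO table, so each table was treated as scaled separately and levels were not tested across the tables. Each table lists 23284 genes, of which 26 were left out because their names were dates or bare numbers, which leaves 23258. The WT columns carry the replicate numbers of the sample titles. The cKO columns are numbered from 0 and the titles from 1, so each cKO column was assigned to its group of genotype, age and fraction only and is called column c0, c1 or c2 here.

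The deposited tables hold no counts, so the depth in fragments is unknown and no counting interval is given. From the commonest ratio of low FPKM values between pairs of libraries, the value of a single fragment relative to the median library lay between 0.553 and 1.679, and 95.3% of the pairs agreed within 0.02 natural log units. The lowest value, of WT P0 monosome 1, is uncertain, because only 43.3% of its pairs agreed. The next lowest was 0.756, of WT E13 total 0. Library sums of FPKM ranged from 391659 to 1130655, and 13340 to 16625 genes had a value above 0.

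Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using the moderated test of limma with an intensity trend in the prior variance, for genes with a mean FPKM of at least 1 over the libraries fitted. A fit per table held its 6 groups and tested 12123 genes in WT and 12302 in the libraries labelled cKO, with 9 and 10 residual degrees of freedom. A joint fit of the 12 groups over 12001 genes, with 19 residual degrees of freedom, served only for differences between effects that were each taken within a table. All tests were two-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. A total of 19 comparisons were made, of which 14 lay within a table. The errors given with log2 fold changes are standard errors (SE), and those given with FPKM are standard deviations (SD). The p-values measure the spread between these libraries, because the labels do not say that each came from a separate animal or litter. The fits also took the fractions as independent, although the check below points to WT fractions that share a sample. The residual degrees of freedom may therefore exceed those of independent samples.

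The comparisons, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined, and the lists described in the text were selected from the 35 after their results were seen. The 35 gene lists hold 761 members, of which 733 were matched by symbol, 8 by a synonym and 20 not at all, and 34 lists had measured members. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Counts of members called are given over all genes and adjusted over the list alone. In each comparison the text names Elavl1, up to 6 higher and 6 lower called genes with the largest fold change, and up to 4 members of each list it describes, taken in order of adjusted p. The largest changes were limited to genes with a group mean of at least 5 FPKM and no overlap between the libraries compared, or the same sign without each library in turn for an interaction. Predicted genes and small RNA genes were excluded from them. Some genes that meet this rule are not reported here. Ribosomal protein, globin and histone genes have close paralogs or pseudogenes and the kit does not keep the strand, so their values are uncertain.

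Whether equal replicate numbers mark fractions of one sample was checked by correlating, across genes, the deviations of libraries from their group means. At P0 the 9 correlations of equal numbers in WT ran from 0.207 to 0.734 and each exceeded those of unequal numbers. At E13 the correlation was 0.411 between monosome and polysome RNA, but -0.512 and -0.538 between total RNA and those fractions, so the total RNA numbers of the WT E13 libraries appear crossed. A replicate block was therefore run as an alternative, once with the numbers as given and once with the WT E13 total numbers exchanged. It lay within age except for P0 against E13, where it joined equal numbers across the ages. Those libraries cannot come from one sample, and their correlations ran from -0.197 to 0.173.

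Other alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, rescaling of each library by its median ratio to the geometric mean within its table, quantile normalization, a fit of only the groups compared, a threshold of at least 2-fold beside the adjusted p, and each library left out in turn. The block with exchanged numbers and a fit without cKO E13 polysome c0 and cKO P0 total c0, which stand apart from their groups, were added after the data were seen. The procedure was tested on simulated data in which 200 genes were changed, 66 of them 4-fold, and a further list of genes was raised 2-fold. It called 59.1% to 98.5% of those 66 over the 19 comparisons, and up to 6.67% of the genes it called were unchanged ones. The simulated noise was independent between genes and libraries. Far fewer genes were changed than limma called for age or fraction in the real data, so these shares need not hold there. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.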

Results

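The data comprised 31 libraries in 12 groups of genotype, age and RNA fraction. WT libraries numbered 2 per fraction at E13 and 3 per fraction at P0. Of the libraries labelled cKO, 3 monosome, 3 polysome and 2 total RNA libraries came from E13, and 2 monosome, 3 polysome and 3 total RNA libraries came from P0. The deposited FPKM values do not give the depth in fragments, so small differences between lowly expressed genes were not interpreted. The labels name the genotypes as WT and cKO and do not name the Cre driver or the part of Elavl1 that was removed.

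Elavl1, the targeted gene, lies on chromosome 8 from 4285382 to 4325413 (GRCm38, minus strand, 6 exons). Its mRNA was present in every library labelled cKO, and its level there was not below that of WT in monosome or total RNA. At E13, Elavl1 measured 82.0 ± 1.92 FPKM (SD, n = 3) in cKO monosome RNA and 27.9 ± 20.4 (n = 2) in WT monosome RNA. E13 total RNA held 48.9 ± 9.11 FPKM (n = 2) in cKO and 33.98 ± 7.80 (n = 2) in WT. In E13 polysome RNA the order was the opposite, with 29.4 ± 0.918 FPKM (n = 3) in cKO and 51.5 ± 12.9 (n = 2) in WT. At P0 the cKO means were 27.2 ± 3.77 FPKM in monosome (n = 2), 19.2 ± 3.29 in polysome (n = 3) and 23.8 ± 5.47 in total RNA (n = 3), beside WT means of 10.3 ± 2.01, 23.2 ± 2.62 and 14.6 ± 1.01 (n = 3 each). These levels come from separately scaled tables and were not tested against each other. A value per gene does not show which exons the reads cover, so the deletion itself was not examined here.

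**Figure D1:**
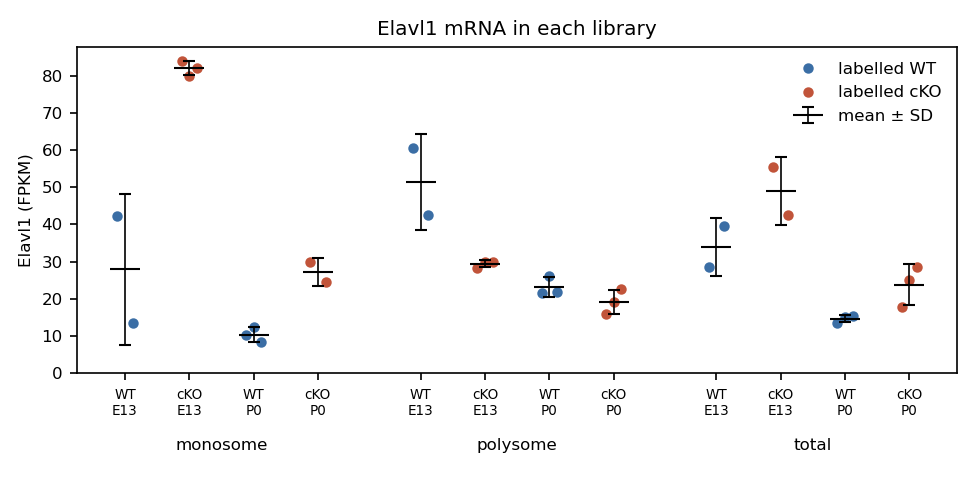
Elavl1 FPKM in each library (points), with the mean and SD of each group (bars), by fraction, age and genotype label. In the libraries labelled cKO the E13 monosome mean of 82.0 lies above the polysome mean of 29.4, while in WT the monosome mean of 27.9 lies below the polysome mean of 51.5.

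The WT comparison of P0 with E13 asked how the neocortical transcriptome changes between these ages. In total RNA, the cell cycle list fell as a whole: all 35 measured members were lower at P0, with a median log2 fold change of -3.20 (n = 3 and 2 libraries). Among them were Mcm2, a subunit of the replicative helicase (-3.31 ± 0.18, SE), Mcm3 (-3.54 ± 0.20), Nusap1 (-3.34 ± 0.20) and Tpx2 (-3.34 ± 0.21), which act on the mitotic spindle. Genes of intermediate progenitors, which divide to form neurons, were lower for 10 of 11 members, with the proneural factors Neurog2 (-4.72 ± 0.27) and Neurog1 (-3.09 ± 0.18), Mfng (-3.76 ± 0.24) and the Notch ligand Dll1 (-2.16 ± 0.18). Of 20 radial glia genes, 14 were lower and 4 higher, the lower ones including Pax6 (-3.12 ± 0.25), Gli3 (-2.86 ± 0.22), Dach1 (-3.16 ± 0.24) and Sox3 (-3.56 ± 0.29). Synapse and vesicle genes were higher for 34 of 37 members and lower for 1, among them Stx1a of the vesicle fusion machinery (3.47 ± 0.22), the scaffold Dlg2 (4.24 ± 0.27) and the calmodulin-binding Nrgn (5.58 ± 0.39). Genes of the neurite cytoskeleton were higher for 25 of 27 members, with Mapt, which encodes tau (4.97 ± 0.36), Stmn2 (3.55 ± 0.24), Gap43 (4.04 ± 0.30) and Nefm (3.03 ± 0.23). Upper-layer neuron genes were higher for 9 of 14 members, with Pou3f1 (3.64 ± 0.43), Lmo4 (2.89 ± 0.26) and Cux2 (1.54 ± 0.23). For each of these lists the count adjusted over the list alone was the same. Camera gave adjusted p-values of 2.47e-19 for cell cycle, 4.63e-06 for intermediate progenitors, 0.0013 for radial glia, 4.05e-15 for synapse, 6e-12 for neurite and 0.000707 for upper-layer genes. None of these passed with an estimated correlation, where the adjusted p was 0.118 for cell cycle, intermediate progenitor, synapse and neurite genes, 0.34 for radial glia and 0.346 for upper-layer genes.

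The largest WT increases in total RNA were of Ptgds, a prostaglandin D synthase (7.02 ± 0.67), the neuropeptide genes Nts (6.16 ± 0.48) and Npy (5.60 ± 0.44), Nrgn, Sla (5.51 ± 0.34) and the dynein chain Dync1i1 (5.20 ± 0.38). The largest decreases were of the embryonic globins Hbb-y (-12.01 ± 0.41) and Hba-x (-9.58 ± 0.48), the chromatin protein Hmga2 (-5.23 ± 0.63), the neurogenic factor Nhlh1 (-4.89 ± 0.42) and Neurog2. Hmga2 measured 0.064 to 0.111 FPKM in the P0 libraries, under the 1 FPKM added before taking logs. Its value therefore depends mainly on the E13 level and understates the fold change in FPKM. The embryonic globin Hbb-bh1 was listed at 0 in every WT P0 library. Elavl1 itself fell by 1.14 in total RNA (SE 0.34, adjusted p = 0.0105), by 1.16 in monosome RNA (adjusted p = 0.00905) and by 1.10 in polysome RNA (adjusted p = 0.0119). Each of these Elavl1 calls ended without one E13 library: -0.92 without total 1 (adjusted p = 0.119), -0.37 without monosome 0 (adjusted p = 0.286) and -0.85 without polysome 0 (adjusted p = 0.129). The RNA-binding protein list moved both ways, with 9 members higher and 13 lower of 33 over all genes and over the list alone, and camera gave an adjusted p of 0.628. Its strongest members were Igf2bp1 (-2.80 ± 0.22), Igf2bp2 (-3.31 ± 0.31), Igf2bp3 (-2.17 ± 0.19) and the splicing regulator Ptbp1 (-2.44 ± 0.25). Of 28 textbook HuR target mRNAs, 11 were lower and 2 higher, counts that were the same adjusted over the list alone. The lower ones included the cyclins Ccnb1 (-4.51 ± 0.35) and Ccna2 (-3.98 ± 0.49), the higher ones were Gap43 and Myc (1.81 ± 0.21), and the list did not pass camera (adjusted p = 0.0558).

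In WT monosome and polysome RNA, all 35 cell cycle genes were lower at P0, with medians of -2.73 in monosome and -3.34 in polysome RNA, and synapse genes were higher for 32 of 37 members in monosome and 34 in polysome RNA. Camera gave 9.58e-15 and 1.3e-16 for the cell cycle list, and the adjusted p was 0.17 and 0.136 with an estimated correlation. For the synapse list camera gave 2.33e-14 and 1.73e-15, again with 0.17 and 0.136 as the adjusted p with an estimated correlation. Neurog2 fell by 5.60 (SE 0.27) in polysome RNA and by 4.47 in monosome RNA, where Neurog1 was listed at 0 in all P0 libraries. Among the largest increases were Gabra5, a GABA receptor subunit, in monosome RNA (5.39 ± 0.25) and the transcription factor Mef2c in monosome (4.75 ± 0.41) and polysome RNA (5.44 ± 0.41). In polysome RNA, 47 of 49 large-subunit ribosomal protein genes (median -1.34) and 32 of 33 small-subunit genes (median -1.48) were lower at P0, with Rps26 at -2.15 ± 0.37. In total RNA 22 large-subunit genes (20 adjusted over the list alone) and 21 small-subunit genes (23 adjusted over the list alone) were lower, and in monosome RNA 16 (6 adjusted over the list alone) and 8 (2 adjusted over the list alone) were. Camera gave 6.89e-07 and 6.13e-06 for both subunits in polysome RNA and 0.000464 and 0.000707 in total RNA. The adjusted p was 0.525 in polysome and 0.663 in total RNA with an estimated correlation. Median ratio rescaling left 41 and 30 of these genes lower in polysome RNA, 11 and 11 in total RNA and 3 and 2 in monosome RNA. The elongation factor gene Eef1a1 was listed at 0 FPKM in every P0 monosome library of either genotype and between 2251 and 22280 FPKM elsewhere. For this and the other genes listed at 0 in whole groups, the tables do not show whether the RNA was absent or the gene was left unquantified.

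Across genes, limma called 6339 genes in WT total RNA (2961 higher and 3378 lower), 6807 in monosome RNA (2478 and 4329) and 6918 in polysome RNA (2870 and 4048) of 12123 tested. With a block on equal replicate numbers across the ages, which do not mark shared samples, the counts were 6463, 7036 and 7047. The median of all genes was -0.12, -0.27 and -0.19, and median ratio rescaling split the called genes into 3269 higher and 2890 lower in total, 3174 and 3279 in monosome and 3269 and 3354 in polysome RNA. The sex-linked genes Eif2s3y (2.71 ± 0.82 in total RNA) and Ddx3y (1.48 ± 0.56) were called higher at P0 in every fraction, and Kdm5d in none. Ddx3y was listed at 0 in WT E13 monosome 0, polysome 0 and total 1, and at 1.72 to 7.00 FPKM at P0. A difference in sex make-up may therefore enter the age comparison, which was not tested.

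**Figure D2:**
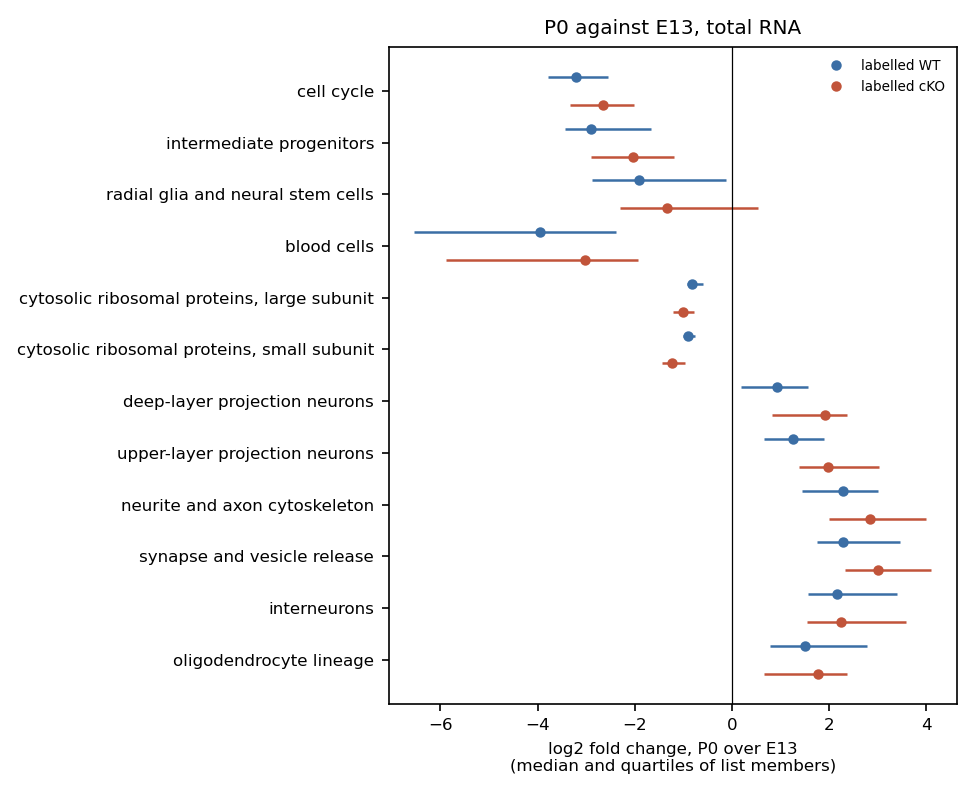
Median log2 fold change of P0 over E13 in total RNA (points) with the quartiles of list members (lines) for selected gene lists and each genotype label. The medians of cell cycle genes lie below 0 and those of synapse and neurite genes above 0 under both genotype labels. In WT the medians are -3.20 for cell cycle and 2.29 for synapse genes.

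In total RNA of the libraries labelled cKO, 33 of 34 cell cycle genes were lower at P0 (median -2.66), including Ube2c (-4.21 ± 0.28), Birc5 (-4.02 ± 0.29), Cdk1 (-3.46 ± 0.26) and Cdk2 (-2.99 ± 0.20; n = 3 and 2 libraries). Intermediate progenitor genes were lower for 10 of 11 members, with Mfng (-3.69 ± 0.25), Neurog2 (-3.60 ± 0.31), Neurog1 (-2.92 ± 0.26) and Btg2 (-2.87 ± 0.27). Of 20 radial glia genes, 13 were lower and 5 higher (median -1.33, beside -1.92 in WT). For that list the genotype by age interaction had a median of 0.55 with 0 of 20 genes called by limma (0 adjusted over the list alone), and 0.0078 from camera (adjusted p = 0.632 with an estimated correlation). Synapse genes were higher for 33 of 37 members, led by Dlg2 (5.03 ± 0.25), Snap25 (5.36 ± 0.31), Syt4 (5.10 ± 0.32) and Vamp2 (3.38 ± 0.22). Upper-layer genes were higher for 11 of 13 members and neurite genes for 25 of 27, with Mapt at 6.01 ± 0.45. The counts adjusted over the list alone were the same, apart from 1 intermediate progenitor gene that was then also higher. Camera gave 1.9e-18 for cell cycle, 1.85e-05 for intermediate progenitor, 0.00291 for radial glia, 1.4e-14 for synapse, 2.7e-05 for upper-layer and 1.97e-11 for neurite genes. With an estimated correlation the adjusted p was 0.0438 for the cell cycle list, 0.158 for radial glia and 0.155 for each of the other 4. The cell cycle list also passed with an estimated correlation in cKO monosome RNA (33 of 34 members lower over all genes, 34 adjusted over the list alone, median -2.41, adjusted p = 0.0449). Those were the only 2 of 646 pairs of list and comparison to do so, against 197 with the preset correlation.

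In cKO total RNA the largest increases were of Ptgds (6.94 ± 0.53), the kinase subunit Camk2b (6.84 ± 0.52), Npy (6.78 ± 0.40), Dync1i1 (6.14 ± 0.39) and Mef2c (6.12 ± 0.34), and the neuropeptide gene Cck was listed at 0 in both cKO E13 total RNA libraries. The largest decreases were of Hbb-y (-12.26 ± 0.62), Hba-x (-10.96 ± 0.53), Hmga2 (-6.82 ± 0.31), the retinoic acid binding protein gene Crabp2 (-5.52 ± 0.34) and Rspo1 (-4.98 ± 0.39). Hmga2 again lay under the added 1 FPKM at P0, at 0.102 to 0.117 FPKM. Elavl1 fell by 1.02 in cKO total RNA (SE 0.23, adjusted p = 0.00128), by 1.56 in monosome RNA (adjusted p = 2.43e-05) and by 0.60 in polysome RNA (adjusted p = 0.0193). The polysome call ended without E13 polysome c2 (-0.59, adjusted p = 0.0520) or without P0 polysome c0 (-0.49, adjusted p = 0.0987). Ribosomal protein genes were lower in cKO polysome RNA for 42 of 49 large-subunit (43 adjusted over the list alone) and 32 of 33 small-subunit members, with camera adjusted p-values of 2.42e-07 and 1.31e-06. The adjusted p was 0.58 and 0.558 with an estimated correlation. In cKO monosome RNA their medians were 0.49 and 0.47, with 7 large-subunit genes higher (0 adjusted over the list alone) and 1 of either subunit lower (0 and 1 adjusted over the list alone), and neither subunit passed camera (adjusted p = 0.13 and 0.303).

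limma called 6267 genes in cKO total RNA (3417 higher and 2850 lower), 5986 in monosome RNA (3231 and 2755) and 7000 in polysome RNA (3740 and 3260) of 12302 tested. The age effects of both genotypes, which share no library, were compared across 12001 genes, which are not independent replicates. Pearson's r was 0.946 in total, 0.919 in monosome and 0.920 in polysome RNA. Of the 4986 genes called in total RNA of both genotypes, 4984 had the same direction, with 2614 higher in both where independent lists would share 816 and 2370 lower in both where they would share 770.

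The comparison of polysome with monosome RNA asked which mRNAs sat with several ribosomes and which with subunits or single ribosomes. In WT, mRNAs of ribosomal proteins lay towards the monosome pool at both ages. At E13 all 33 small-subunit genes were lower in polysome RNA (median log2 fold change -2.10, n = 2 and 2) and 45 of 49 large-subunit genes were lower and 1 higher (median -1.97). The small-subunit genes included Rps12 (-3.94 ± 0.43), Rps27l (-3.40 ± 0.36), Rps21 (-3.38 ± 0.37) and Rps20 (-3.29 ± 0.37). At P0 all 33 small-subunit genes (median -2.97, n = 3 and 3) and 46 of 49 large-subunit genes (median -2.85) were lower, with Rps12 at -5.04 ± 0.35, Rpl12 at -3.78 ± 0.26 and Rplp0 at -3.70 ± 0.29. Non-coding hosts of small nucleolar RNAs were lower for 11 of 12 members at E13 and 12 of 12 at P0, with Snhg8 (-3.76 ± 0.33 and -3.67 ± 0.27) and Snhg12 (-2.57 ± 0.30 and -3.23 ± 0.25). Nuclear long non-coding RNAs were lower for 9 of 12 members at either age, with Rian (-3.52 ± 0.43 and -4.84 ± 0.35) and Neat1 (-2.37 ± 0.29 and -2.88 ± 0.23), and 1 member was higher. These counts were the same adjusted over the list alone. At E13 camera gave 7.01e-15 for either ribosomal list, 4.58e-07 for the small nucleolar RNA hosts and 0.00303 for nuclear non-coding RNAs, and the adjusted p was 0.73, 0.73 and 0.524 with an estimated correlation. At P0 camera gave 2.17e-22 and 3.33e-24 for small- and large-subunit genes, 3.54e-09 for the hosts and 0.00024 for nuclear non-coding RNAs, and the adjusted p was 0.504, 0.504, 0.504 and 0.224 with an estimated correlation.

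Neurite cytoskeleton mRNAs lay towards WT polysomes. At E13, 19 of 27 were higher there and 1 lower (median 1.19), with Crmp1 (2.01 ± 0.28), Dpysl5 (1.94 ± 0.26), Marcks (1.88 ± 0.25) and the kinesin Kif5c (1.74 ± 0.25), and at P0, 24 were higher (25 adjusted over the list alone, median 1.61), with Gap43 at 2.72 ± 0.27. Cell cycle mRNAs were higher in polysome RNA for 24 of 35 members at E13 (median 1.57), with Mcm5 (2.77 ± 0.28), Mcm3 (2.48 ± 0.22), Mcm4 (2.02 ± 0.20) and Mcm2 (1.99 ± 0.20), and for 23 at P0 (24 adjusted over the list alone, median 0.82), with 1 lower at either age. Camera gave 0.00469 and 6.76e-06 for the neurite list and 0.000191 and 0.0286 for the cell cycle list at E13 and P0. With an estimated correlation the adjusted p was 0.744 and 0.656 for neurite and 0.744 and 0.988 for cell cycle genes. Textbook HuR target mRNAs were higher in polysome RNA for 15 of 28 members at E13 (16 adjusted over the list alone) and 19 at P0, and 4 were lower at either age. The higher ones included Trp53, which encodes p53 (2.64 ± 0.24 and 2.31 ± 0.20), and the lower ones Xiap, an inhibitor of apoptosis (-1.90 ± 0.24 and -2.26 ± 0.20), while the list did not pass camera (adjusted p = 0.112 and 0.149). Initiation factor mRNAs split, with 21 higher and 10 lower of 44 at E13 and 20 and 12 at P0 (23 higher adjusted over the list alone), and did not pass camera (0.325 and 0.96). Pabpc1, which encodes the poly(A) binding protein (-3.39 ± 0.31 and -3.78 ± 0.25), and Eif4ebp2 (-2.24 ± 0.24 and -2.48 ± 0.20) lay towards monosomes, and Eif3b (2.79 ± 0.26 and 2.77 ± 0.22) and Eif4a3 (2.95 ± 0.32 and 2.84 ± 0.26) towards polysomes. Elavl1 was higher in WT polysome RNA at both ages, by 1.05 ± 0.37 at E13 (adjusted p = 0.0272) and 1.11 ± 0.30 at P0 (adjusted p = 0.00540). The E13 call ended with median ratio rescaling (0.78, adjusted p = 0.0797), without a filter (adjusted p = 0.0579), with only the groups compared (adjusted p = 0.142), without monosome 1 (0.25, adjusted p = 0.480) and without polysome 0 (0.79, adjusted p = 0.169).

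The largest shifts towards WT polysomes at E13 were of Akr1b3 (3.65 ± 0.77), Hnrnpa2b1 (3.25 ± 0.24), Rrp1 (3.14 ± 0.25), Aamp (3.14 ± 0.27), Eno1 (3.11 ± 0.37) and Psmd2 (3.05 ± 0.20), and those towards monosomes included the imprinted non-coding RNA H19 (-4.29 ± 0.52) and Rpl41 (-4.07 ± 0.55). limma called 6466 genes at E13 (3951 higher and 2515 lower) and 7255 at P0 (4793 and 2462), or 6813 and 7597 with a replicate block. The median of all genes was 0.24 and 0.30, and with median ratio rescaling the split was 3005 higher and 3080 lower at E13 and 3435 and 3361 at P0. A fit of the E13 groups alone called 3964 genes.

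**Figure D3:**
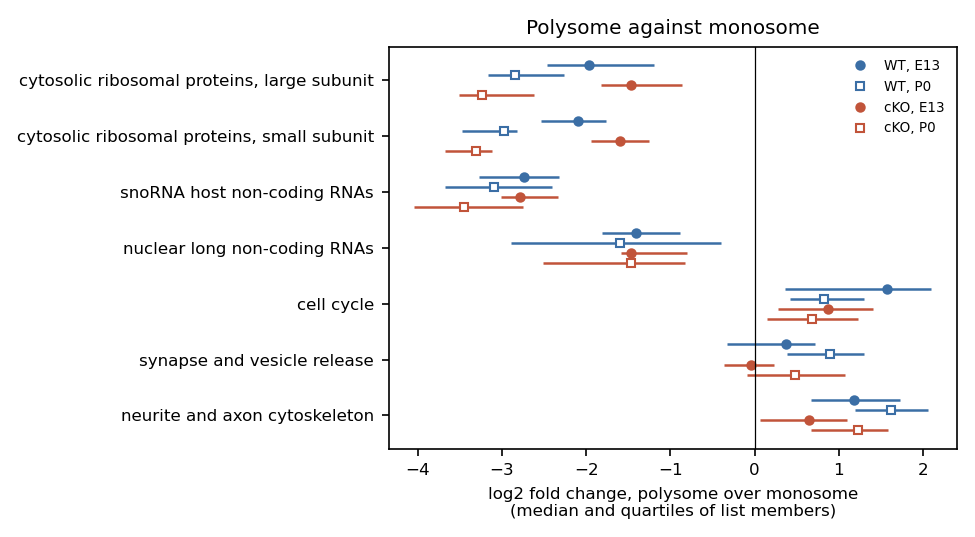
Median log2 fold change of polysome over monosome RNA (points) with the quartiles of list members (lines) for 7 gene lists at each age and genotype label. Ribosomal protein and small nucleolar RNA host genes lie below 0 in all comparisons, with medians of -2.10 at E13 and -2.97 at P0 for small-subunit genes in WT, and neurite genes lie above 0.

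In the libraries labelled cKO, ribosomal protein mRNAs also lay towards monosomes. At E13, 32 of 33 small-subunit (median -1.60, n = 3 and 3) and 38 of 49 large-subunit genes (40 adjusted over the list alone, median -1.47) were lower in polysome RNA, with Rps27l (-3.05 ± 0.35) and Rpl41 (-3.37 ± 0.38). At P0, 32 of 33 (median -3.31, n = 3 and 2) and 46 of 49 (median -3.24) were lower, with Rps12 at -5.10 ± 0.45 and Rpl39 at -4.21 ± 0.38, and 1 large-subunit gene was higher at either age. Small nucleolar RNA hosts were lower for 11 of 11 members at either age, with Snhg8 at -3.04 ± 0.28 and -3.99 ± 0.32. Neurite mRNAs were higher for 13 of 27 members at E13 (median 0.64), with Stmn4 (1.57 ± 0.27) and Tubb3 (1.36 ± 0.34), and for 19 at P0 (median 1.22), with Stmn4 (2.39 ± 0.30) and Gap43 (2.43 ± 0.33). Blood cell mRNAs, mostly globins, were higher in E13 polysome RNA for 8 of 12 members (median 1.99). At E13 camera gave 2.29e-10 and 8.85e-10 for small- and large-subunit genes, 3.6e-08 for the hosts, 0.0477 for neurite and 0.0137 for blood genes. With an estimated correlation the adjusted p was 0.705, 0.705, 0.505, 0.774 and 0.705. At P0 camera gave 5.75e-20 and 5.45e-22 for both subunits, 2.07e-08 for the hosts and 7.55e-05 for neurite genes, and the adjusted p was 0.524, 0.551, 0.476 and 0.766 with an estimated correlation. Elavl1 fell by 1.45 from monosome to polysome RNA in the E13 libraries labelled cKO (SE 0.21, adjusted p = 2.39e-05), and its P0 value was -0.49 ± 0.23 (adjusted p = 0.0915). The largest shifts towards polysomes at E13 were of Akr1b3 (4.58 ± 0.62), Hbb-b2 (3.62 ± 0.79) and Aamp (2.69 ± 0.25). limma called 5548 genes at E13 (2797 higher and 2751 lower) and 6008 at P0 (3081 and 2927).

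Whether the distribution between polysomes and monosomes changes with age was tested as an interaction within each table. In WT, Basp1 (2.69 ± 0.39), the kinase Ptk2b (2.49 ± 0.33), Prrt2 (2.47 ± 0.30) and Marcksl1 (2.46 ± 0.40) lay further towards polysomes at P0 than at E13. Of 37 synapse genes 6 rose (8 adjusted over the list alone), including the vesicle protein gene Vamp2 (2.02 ± 0.39), and camera gave 0.00273 (adjusted p = 0.651 with an estimated correlation). The extracellular matrix gene Bgn (-2.70 ± 0.41), Tcerg1l (-2.36 ± 0.28) and Alas2 of heme synthesis (-2.24 ± 0.31) moved the other way. Of 12 endothelial genes 2 fell (9 adjusted over the list alone), including the glucose transporter gene Slc2a1 (-1.71 ± 0.36), with 7.42e-07 from camera (adjusted p = 0.651 with an estimated correlation). The call of Vamp2 ended without E13 polysome 0 (1.84, adjusted p = 0.0584) and that of Slc2a1 without E13 monosome 0 (-1.49, 0.0918), E13 polysome 0 (-1.27, 0.0775) or P0 monosome 2 (-1.61, 0.05505). In total 513 genes were called (366 higher and 147 lower), 582 with a replicate block and 25 with only the groups compared, and median ratio rescaling split them 236 and 153. Single libraries moved the count: 1937 without E13 monosome 1, 1131 without E13 polysome 1, 115 without E13 monosome 0, 112 without E13 polysome 0, 254, 172 and 113 without P0 monosome 0, 1 and 2, and 222 and 192 without P0 polysome 1 and 2. Elavl1 was at 0.06 ± 0.48 (adjusted p = 0.958).

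In the libraries labelled cKO, ribosomal protein mRNAs lay further from polysomes at P0 than at E13. Of 49 large-subunit genes 28 fell (41 adjusted over the list alone, median -1.69), with Rpl21 (-2.25 ± 0.47) and Rpl6 (-2.03 ± 0.43), and of 33 small-subunit genes 18 fell (31 adjusted over the list alone, median -1.71). Secretory pathway genes fell for 8 of 25 members (14 adjusted over the list alone), with the translocon proteins Ssr1 (-1.95 ± 0.33) and Ssr3 (-1.74 ± 0.32), and blood cell genes for 6 of 12 (10 adjusted over the list alone). Camera gave 1.51e-20, 1.71e-16, 4.12e-06 and 3.43e-07 for these 4 lists, and the adjusted p was 0.65, 0.65, 0.408 and 0.408 with an estimated correlation. The same ribosomal lists in WT had medians of -0.77 and -0.84, with 1 gene called, Rpl21 (-1.58 ± 0.41, adjusted p = 0.0421), whose call ended with a replicate block (adjusted p = 0.0681) and without any library compared except E13 monosome 1 and E13 polysome 1 (adjusted p = 0.0563 to 0.158). Whether this shift with age differs between the genotypes was not tested, and unlike counts of calls do not show that it does. The largest decreases in the libraries labelled cKO were of Bgn (-3.75 ± 0.49) and the globins Beta-s (-3.46 ± 0.71), Hbb-b1 (-3.30 ± 0.56) and Hba-a1 (-3.13 ± 0.61). Among the largest increases was Mapk8ip3, which encodes an adaptor of axonal transport (2.57 ± 0.39). Without P0 monosome c0 the calls of Rpl21 (-2.07, adjusted p = 0.0702), Rpl6 (-1.92, 0.0689) and Beta-s (-3.32, 0.0585) ended. limma called 959 genes (306 higher and 653 lower). The count was 173 without P0 monosome c1, 195 without P0 monosome c0, 347 and 382 without P0 polysome c1 and c2, 540 without E13 monosome c2 and 1895 without the pair of libraries that stand apart. Elavl1 was at 0.96 ± 0.31 (adjusted p = 0.0644).

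The interaction of age with polysome against total RNA called 1 gene in WT, Snora65, a small nucleolar RNA that was chosen for the text after its values were seen. It measured 44.2 and 167 FPKM in the WT E13 total RNA libraries, up to 0.467 FPKM in those of P0, and was listed at 0 in every WT polysome library. The libraries labelled cKO listed it at 0 and 411 FPKM in E13 total RNA, at 0, 0 and 341 in E13 monosome RNA and at 0 in all others, so replicates within a group differed as widely as the ages, and no age change of this gene is claimed. limma gave an unadjusted p under 0.05 for 466 genes, and the count was 2 without E13 polysome 0 or P0 polysome 2, 5 without E13 total 0 and 3 with the exchanged E13 total numbers. In the libraries labelled cKO limma called 0 genes, with an unadjusted p under 0.05 for 684. At this number of libraries a simulated 4-fold change in FPKM + 1 was called for 74.2% of genes in WT and 62.1% in cKO. Elavl1 was at 0.04 ± 0.48 in WT (adjusted p = 0.999) and 0.42 ± 0.31 in the libraries labelled cKO (adjusted p = 0.932).

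Whether the change between E13 and P0 differs between the genotypes was tested in each fraction. Aldoc, an aldolase of astrocytes and radial glia (chromosome 11, 78322968 to 78327781), rose more, or fell less, from E13 to P0 in the libraries labelled cKO in total (2.83 ± 0.49, adjusted p = 0.0269), monosome (3.05 ± 0.49, adjusted p = 0.00597) and polysome RNA (3.49 ± 0.46, adjusted p = 0.000212). In total RNA it went from 127 ± 31.5 to 57.3 ± 13.9 FPKM in WT (n = 2 and 3) and from 27.2 ± 0.0351 to 90.1 ± 8.66 in cKO (n = 2 and 3). Ndrg2 (chromosome 14, 51905271 to 51914158) differed in the same direction in total (2.32 ± 0.41, adjusted p = 0.0269) and polysome RNA (2.94 ± 0.39, adjusted p = 0.000212). The neuronal transcription factor Neurod6 (chromosome 6, 55677822 to 55681263) differed by 3.39 ± 0.57 in monosome and 2.96 ± 0.54 in polysome RNA. Of 11 intermediate progenitor genes, 2 were called higher in polysome RNA (5 adjusted over the list alone), Eomes (2.63 ± 0.51) and Neurog2 (1.98 ± 0.40), and 1 in monosome RNA (8 adjusted over the list alone), Neurog2 (1.86 ± 0.43). Camera gave 4.75e-05 in polysome and 1.72e-05 in monosome RNA, and the adjusted p was 0.259 and 0.173 with an estimated correlation. Blood cell genes fell more in the polysome libraries labelled cKO for 3 of 10 members (3 lower and 1 higher adjusted over the list alone), with 0.00226 from camera (adjusted p = 0.375 with an estimated correlation). In total RNA the calls of Aldoc and Ndrg2 ended without any library except WT E13 1, WT P0 2 and cKO P0 c0 (adjusted p = 0.0762 to 0.385). The monosome call of Aldoc ended without WT E13 1 (3.003, adjusted p = 0.0678) or cKO P0 c0 (2.88, 0.0603), and its polysome call only with a fit of the groups compared (0.151). The call of Neurod6 ended without WT E13 1 in polysome (2.11, adjusted p = 0.225) and monosome RNA (2.60, 0.0724), and in monosome RNA also without cKO P0 c0 (3.40, 0.0603) or c1 (3.39, 0.106). The polysome calls of Eomes and Neurog2 ended without WT E13 1, WT P0 0, cKO E13 c0 or any cKO P0 library (adjusted p = 0.0534 to 0.225), and that of Neurog2 also without WT P0 1 (0.0689). The monosome call of Neurog2 ended without any library except WT E13 0, WT P0 2 and cKO E13 c1 (adjusted p = 0.0601 to 0.315). Median ratio rescaling ended the total RNA calls of Aldoc (2.71 ± 0.49, adjusted p = 0.0544) and Ndrg2 (2.19 ± 0.40, 0.0544) and the calls of Neurog2 in polysome (1.75 ± 0.41, 0.0770) and monosome RNA (1.69 ± 0.43, 0.184). Quantile normalization ended every call of these 5 genes (adjusted p = 0.0507 to 0.417) except the polysome calls of Aldoc and Ndrg2. A fit of only the groups compared also ended the polysome calls of Neurod6, Eomes and Neurog2 (adjusted p = 0.151 to 0.167), the monosome calls of Neurod6 (0.0667) and Neurog2 (0.0876) and the total RNA call of Ndrg2 (0.108). A pseudocount of 0.1 ended the polysome calls of Eomes and Neurog2 (both 0.0573), that pseudocount, one of 5 and no filter ended the monosome call of Neurog2 (0.0635, 0.0632 and 0.0565), and no filter ended both total RNA calls (0.104).

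**Figure D4:**
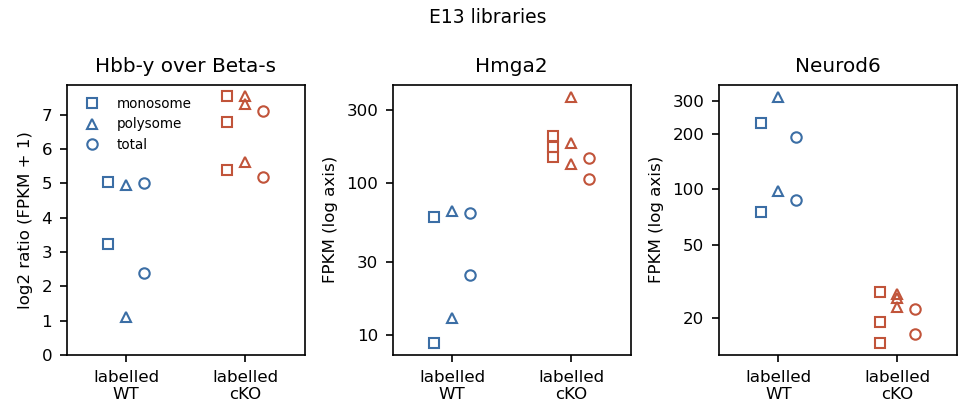
Embryonic to adult globin ratio (log2 of Hbb-y over Beta-s), Hmga2 FPKM and Neurod6 FPKM (log axes) in each E13 library, by fraction and genotype label. The Hmga2 values run from 8.84 to 65.1 FPKM in WT and from 106 to 367 in cKO, and the Neurod6 values from 75.9 to 318 in WT and from 14.7 to 27.6 in cKO.

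The E13 libraries of both genotype labels differed in several such levels, which were not tested. The FPKM levels were read from separately scaled tables, while the globin ratio was taken within each library. Hmga2 measured 8.84 to 65.1 FPKM in the 6 WT and 106 to 367 in the 8 cKO libraries of E13, Neurod6 75.9 to 318 and 14.7 to 27.6, and the log2 ratio of Hbb-y to Beta-s 1.12 to 5.03 and 5.18 to 7.56. limma called 2 genes in total RNA (both higher), 38 in monosome RNA (36 higher and 2 lower) and 63 in polysome RNA (55 higher and 8 lower) of 12001, with an unadjusted p under 0.05 for 733, 1769 and 1966. Median ratio rescaling left 0, 6 (4 higher and 2 lower) and 19 (11 higher and 8 lower). In polysome RNA the count was 950 without cKO E13 c1, 246 without WT E13 0, 2 without WT E13 1, 7 and 13 without WT P0 0 and 1, 9 without cKO E13 c0, and 10, 8 and 6 without cKO P0 c0, c1 and c2. In monosome RNA it was 225, 10 and 20 without cKO E13 c1, c0 and c2, 119 and 0 without WT E13 0 and 1, 3 and 5 without WT P0 0 and 1, and 0 and 2 without cKO P0 c0 and c1. In total RNA it was 4 without WT E13 1, 1 without cKO P0 c1, and 0 without WT E13 0, WT P0 0 or 1, cKO E13 c0 or c1, or cKO P0 c2. Elavl1 was at 0.12 ± 0.42 in total (adjusted p = 0.987), -0.40 ± 0.42 in monosome (adjusted p = 0.692) and 0.50 ± 0.39 in polysome RNA (adjusted p = 0.569).

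Whether the distribution between polysomes and monosomes differs between the genotypes was tested at each age. At E13 Elavl1 was the only gene of 12001 called: its polysome over monosome ratio was lower in the libraries labelled cKO by -2.495 ± 0.42 on the log2 scale (adjusted p = 0.0241, n = 3 and 3 in cKO, 2 and 2 in WT). The call ended with median ratio rescaling (-2.23 ± 0.40, adjusted p = 0.0705), with only the groups compared (adjusted p = 0.995), and without any of 6 libraries: WT monosome 1 (-1.70, adjusted p = 0.219), WT polysome 0 (-2.24, 0.0838), cKO monosome c0 (-2.48, 0.0835) and c2 (-2.49, 0.0809), and cKO polysome c0 (-2.47, 0.0807) and c2 (-2.51, 0.0736). Without WT monosome 0 it was -3.29 (adjusted p = 1.07e-05). The unadjusted p was under 0.05 for 1345 genes, and the count of called genes was 342 without cKO polysome c1 and 15 without cKO monosome c1. Other RNA-binding protein genes had smaller values that were not called, with Tardbp at -1.28 ± 0.40, Syncrip at -0.98 ± 0.31 and Khdrbs1 at -0.98 ± 0.33. Tardbp and Khdrbs1 passed only without cKO polysome c1 (adjusted p = 0.0390 and 0.0267). Elavl1 was the 1 of 33 members called (4 lower adjusted over the list alone), with 0.00702 from camera (adjusted p = 0.605 with an estimated correlation). Camera also gave 3.52e-12 for large-subunit ribosomal genes, with a median of 0.47 and 0 genes called by limma (0 adjusted over the list alone, adjusted p = 0.605 with an estimated correlation). At P0 limma called 0 genes, with an unadjusted p under 0.05 for 302. The Elavl1 value there was -1.60 ± 0.39, with an unadjusted limma p of 3.87e-04 and an adjusted p of 0.857.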

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

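The tests of developmental stage, of table scaling, of single libraries for Elavl1 and of the cKO polysome library c0 were chosen only after the results were seen, and the test of any other single library for the ribosomal protein genes was planned. Each value in this part comes from a test of the difference between the effects of 2 ages or 2 genotype labels.

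In the genotype by age interaction, a positive difference is a larger rise, or a smaller fall, from E13 to P0 in the libraries labelled cKO. The 63 genes called in polysome RNA included Aldoc (3.49), Sez6 (3.25), Tiam2 (3.07), Neurod6 (2.96), Ndrg2 (2.94) and Eomes (2.63) as the largest positive differences. Hba-x (-3.26), Slc4a1 (-1.92), Tmem163 (-1.86) and Car2 (-1.74) were the largest negative ones, and Hbb-bh1 and Hsd3b6 were each listed at 0 FPKM in a whole group, so no fold is given. The 38 genes called in monosome RNA included the adult-type globins Beta-s (5.02) and Hbb-b1 (3.63), Sstr2 (3.42), Neurod6 (3.39), Aldoc (3.05), Ppp1r1b (2.67), Slc25a37 (-1.98) and Fam84b (-1.89). The 2 genes called in total RNA were Aldoc (2.83) and Ndrg2 (2.32).

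Scaling of the tables was tested on the polysome genes by rescaling each library to its median ratio. Over all 63 genes, signed by the direction of their call, the median difference was 1.703 (median SE 0.402) after rescaling and 1.838 (SE 0.398) before. These genes were picked by their calls in the same data. Rescaling moved the median of all tested genes only from 0.234 to 0.066, so it could not have brought 1.838 near 0. The test therefore does not decide how far scaling contributed to the calls. The calls of 44 ended, with a median of 1.574 (SE 0.398) after and 1.766 (SE 0.395) before. All 44 estimates came nearer to 0 and 31 of the SE rose, which took the p-value of 33 above the largest p called before, while the other 11 met a stricter threshold because fewer genes passed. Among the genes named above, those whose calls ended were Sez6 (3.25, SE 0.692, then 3.05, SE 0.702) and Tiam2 (3.07, SE 0.654, then 2.89, SE 0.653) in polysome RNA. In monosome RNA they were Beta-s (5.02, SE 1.001, then 4.76, SE 1.005), Hbb-b1 (3.63, SE 0.798, then 3.38, SE 0.8) and Ppp1r1b (2.67, SE 0.552, then 2.44, SE 0.546). In total RNA both calls ended, of Aldoc (2.83, SE 0.486, then 2.71, SE 0.487) and Ndrg2 (2.32, SE 0.407, then 2.19, SE 0.404), and each of these 7 estimates came nearer to 0. An earlier stage of the E13 tissue labelled cKO may contribute: 52 of the 63 genes, or 82.5%, had the sign of the difference between WT E13 polysome 1 and 0, against 54% of all tested genes. The 2 libraries also differed in sex-linked genes, with Xist at 3.42 and Ddx3y at 0 FPKM in polysome 0 and 1.455 and 2.612 in polysome 1. They may differ in other ways too, and both enter the interaction. The shared sign therefore does not separate stage from their other differences. The difference between polysome 1 and 0 had a median of 0.345 in the 55 genes called higher, whose median interaction was 1.83. It ran from -0.622 (Gm7694) to 2.249 (Tiam2) over those genes. The globin ratios of the E13 libraries labelled cKO (5.18 to 7.56) lay above those of WT (1.12 to 5.03). A difference within WT therefore does not measure a stage gap between the labels. An effect of HuR loss remains open as an untested biological explanation.

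Elavl1, which encodes HuR, was the 1 gene called for a genotype difference in its polysome over monosome ratio at E13 (-2.495, SE 0.42), with more of its mRNA in the monosome pool of the libraries labelled cKO. A single library as its cause was tested by leaving out each of the 10. The value nearest to 0 was -1.7032 (SE 0.353), without WT E13 monosome 1, which argues against 1 library as the whole cause, although the call ended there (adjusted p = 0.219) and without WT polysome 0, cKO monosome c0 or c2, or cKO polysome c0 or c2 (adjusted p = 0.0736 to 0.0838). Median ratio rescaling gave -2.2341 (SE 0.399), so the estimate kept most of its size. The median of all genes in this comparison was only -0.179, so rescaling could not have brought -2.495 near 0. The test therefore does not decide how far scaling contributed. The call ended with rescaling (adjusted p = 0.0705) because the estimate fell by a larger share than its SE. It also ended with only the groups compared (adjusted p = 0.995). A candidate explanation is that the altered gene still makes an mRNA with a shorter reading frame that holds fewer ribosomes. Another is an earlier stage of the E13 tissue labelled cKO, where the globin ratio was 5.18 to 7.56 (1.12 to 5.03 in WT). Genotype label and globin ratio differ together, so these explanations cannot be told apart here. Neither was tested, and values per gene do not resolve exons.

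Ribosomal protein mRNAs in the libraries labelled cKO lay further from polysomes at P0 than at E13. In WT the medians of polysome over monosome RNA also fell, from -2.10 to -2.97 (small subunit) and from -1.97 to -2.85 (large subunit). In the libraries labelled cKO the median interaction was -1.696 over 82 genes, 46 of them called lower. Whether this shift differs from that in WT was not tested. Neither the small-subunit nor the large-subunit list passed camera with an estimated correlation. Without the E13 polysome library c0, which stands apart from its group, the median was -1.472, and without any other single library it came no nearer to 0 than -1.556, so no 1 library accounts for it. The number called was 0 and 2 without P0 monosome c0 and c1, 4, 7 and 26 without P0 polysome c2, c1 and c0, 12 and 21 without E13 monosome c2 and c1, and 29 without E13 polysome c0. Reads shared between paralogs and pseudogenes, a change in the make-up of the monosome pool and a biological effect of age remain open, and were not tested.

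The other genes of the cKO age by polysome and monosome interaction, among 959 called, were Nrgn (2.58), Mapk8ip3 (2.57), Dync1i1 (2.504), Vsnl1 (2.49) and Rhof (2.37) in the positive direction. Bgn (-3.75), Beta-s (-3.46), Hbb-b1 (-3.30), Hba-a1 (-3.13), Stac2 (-2.93) and Hbb-y (-2.81) were the largest in the negative direction. In WT, among 513 called, they were Basp1 (2.69), Nrgn (2.65), Ptk2b (2.49), Prrt2 (2.47), Marcksl1 (2.46), Bgn (-2.70), Stx3 (-2.49), Tcerg1l (-2.36), Aqp11 (-2.26), Alas2 (-2.24) and Adss (-2.24). Eef1a1 was listed at 0 in every P0 monosome library of either genotype, so its interactions have no fold, and the tables do not show whether it was absent or left unquantified. The 1 gene of the WT age by polysome and total RNA interaction, Snora65, was listed at 0 in every WT polysome library and at 0 and 411 FPKM in the 2 E13 total RNA libraries labelled cKO.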

How the results depend on the processing

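The block with exchanged WT E13 total RNA numbers and the fit without the libraries that stand apart were chosen only after the data were seen. A replicate block was run for the WT results. It was planned but not run for the cKO results and the genotype interactions, because the cKO columns are numbered apart from the sample titles and were assigned to groups alone. Those results, the interactions of Elavl1 and the ribosomal protein genes among them, rest on an unpaired model by this choice. Equal cKO column numbers were neither checked for pairing nor used as pairs, and how a block on them would move those results is unknown. Where leaving out a library left 1 in its group, that library was assumed to vary like the other groups. The cause of the changes listed here was not tested, except that a 2-fold threshold calls fewer genes by construction.

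Requiring at least 2-fold beside the adjusted p left 3968, 4181 and 4411 genes for WT P0 against E13 in total, monosome and polysome RNA, 4388 for WT polysome against monosome at P0 and 3415 for cKO at E13. A fit of only the groups compared called 3964 genes for WT polysome against monosome at E13, 25 for the WT age by polysome and monosome interaction, 3 for that of polysome and total RNA, 3 and 1 for genotype by age in monosome and polysome RNA, and 0 for genotype by polysome and monosome at E13. A pseudocount of 0.1 called 306 genes for the WT age by polysome and monosome interaction and 22 and 11 for genotype by age in monosome and polysome RNA. A pseudocount of 5 called 1091 and 1500 genes for age by polysome and monosome in WT and cKO, 3 for WT age by polysome and total RNA, 89 and 142 for genotype by age in monosome and polysome RNA and 2 for genotype by polysome and monosome at E13, and gave r = 0.904 between the genotypes' age effects in monosome RNA. Without a filter, the counts were 3 and 1 for age by polysome and total RNA in WT and cKO, 0 and 67 for genotype by age in total and monosome RNA, and 5 and 3 for genotype by polysome and monosome at E13 and P0. Median ratio rescaling left 0, 6 and 19 genes for genotype by age in total, monosome and polysome RNA and 0 for genotype by polysome and monosome at E13, and gave an Elavl1 mean of 12.46 FPKM in WT P0 monosome RNA. Quantile normalization called 3 genes for WT age by polysome and total RNA and 0, 3 and 14 for genotype by age in total, monosome and polysome RNA. The block with exchanged numbers called 3 genes for WT age by polysome and total RNA. Without the libraries that stand apart, 1895 genes were called for the cKO age by polysome and monosome interaction, 19 for genotype by age in polysome RNA and 0 for genotype by polysome and monosome at E13. With an estimated correlation, camera passed 2 pairs of list and comparison.

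Without each library in turn, the WT counts for P0 against E13 ran from 4294 to 5682 in total, 5002 to 6780 in monosome and 5249 to 6778 in polysome RNA, and the cKO counts from 4522 to 6276, 4254 to 5622 and 6159 to 6895. Those for polysome against monosome ran from 5745 to 6163 at E13 and 6513 to 7008 at P0 in WT, and from 4632 to 6071 and 4173 to 5340 in cKO. Those for age by polysome and monosome ran from 112 to 1937 in WT and 173 to 1137 in cKO, and those for age by polysome and total RNA from 1 to 5 in WT and stayed at 0 in cKO by limma, where 684 genes had an unadjusted p under 0.05. Genotype by age ran from 0 to 4 in total, 0 to 225 in monosome and 2 to 950 in polysome RNA. Genotype by polysome and monosome ran from 0 to 342 at E13 and stayed at 0 at P0, with 302 genes at an unadjusted p under 0.05.

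For the 505 results of named genes, 6704 of 7158 alternative values kept direction and side of the threshold, 384 no longer passed, 52 passed only in the alternative, 18 that did not pass changed sign and 0 that passed reversed. Of the 384, 261 arose from leaving out 1 library. Depth in fragments is unknown, so no lower limit of detection can be given for single genes. In simulated data a 2-fold change in FPKM + 1 was called for 55.2% of genes for WT age in total RNA. The share was 2.99% for genotype by age in total RNA and 11.9% for genotype by polysome and monosome. Absence of a call in those interactions therefore says little about changes of that size. The simulation changed few genes, and its noise was independent between genes. The 55.2% therefore does not describe the real WT age comparison, in which 6339 genes were called.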

Other observations

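The test of stage with cell cycle genes was chosen only after the result was seen, and the counts of other splits were planned. Other gene lists, most of them markers of cell types, also moved between E13 and P0 in WT total RNA. A change in the cell types themselves was not tested. Interneuron genes, of cells that migrate into the cortex from ventral forebrain, were higher for 13 of 15 members (13 adjusted over the list alone), with a median log2 fold change of 2.16 and 3.06e-06 from camera (adjusted p = 0.332 with an estimated correlation). Oligodendrocyte lineage genes were higher for 7 of 8 members (7 adjusted over the list alone), with a median of 1.52 and 0.000414 from camera (adjusted p = 0.101 with an estimated correlation). Blood cell genes, which include the embryonic globins, were lower for 9 of 10 members (9 adjusted over the list alone), with a median of -3.96 and 6.56e-06 from camera (adjusted p = 0.101 with an estimated correlation). Choroid plexus and cortical hem genes were lower for 8 of 14 members (8 adjusted over the list alone), with a median of -1.78 and 0.0039 from camera (adjusted p = 0.346 with an estimated correlation). Secretory and membrane protein folding genes were lower for 12 of 25 members (11 adjusted over the list alone), with a median of -0.94 and 0.00541 from camera (adjusted p = 0.617 with an estimated correlation).

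Nuclear-encoded genes of the mitochondrial respiratory chain were lower at P0 in WT monosome RNA for 47 of 74 members (48 adjusted over the list alone), with a median of -0.89 and 0.000492 from camera (adjusted p = 0.842 with an estimated correlation), and for 29 after median ratio rescaling. In total RNA 4 were lower (1 adjusted over the list alone), with a median of -0.26 and 0.123 from camera. In the libraries labelled cKO, astrocyte genes were higher in polysome than in monosome RNA at E13 for 7 of 12 members (7 adjusted over the list alone), with 0.0274 from camera (adjusted p = 0.705 with an estimated correlation). The 4 members of lowest adjusted p in WT at E13 were also called higher there. They were Aldoc (2.93 ± 0.30), Gja1 (1.91 ± 0.41), Apoe (2.01 ± 0.47) and Clu (1.47 ± 0.40). The shift was therefore not particular to the libraries labelled cKO. Counts over the list in WT are not given here. Aldoc also marks radial glia.

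The WT E13 libraries differed in the log2 ratio of the embryonic globin Hbb-y to the adult-type Beta-s, a ratio that falls as definitive red cells replace primitive ones. It was 5.03, 4.94 and 5.00 in monosome 0, polysome 0 and total 1, and 3.25, 1.12 and 2.40 in monosome 1, polysome 1 and total 0. In the 8 E13 libraries labelled cKO it ran from 5.18 to 7.56. Lin28b, a regulator of developmental timing, measured 0.168 to 1.19 FPKM in the WT and 0.544 to 5.37 in the cKO libraries of E13, and the neuronal factor Neurod2 16.8 to 58.6 and 7.25 to 18.6.

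These levels may reflect an earlier stage of the E13 tissue labelled cKO. The hypothesis was tested with the cell cycle list in the genotype by age interaction of total RNA. The median of its 34 members, relative to all genes, was 0.326, while the difference between the WT E13 total libraries of lower and higher globin ratio was -0.405. The sign is opposite to what the hypothesis predicts, but camera with an estimated correlation gave an adjusted p of 0.632, so the test decided nothing.

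For comparisons with 3 libraries on both sides, the 6 libraries can be split in 10 ways, too few for a share under 0.05. For cKO P0 against E13 in polysome RNA the real split called 7000 genes and the highest other split 0, so that 1 of the 10 reached the real count. For WT polysome against monosome at P0 the numbers were 7255 and 0, again 1 of 10. For cKO polysome against monosome at E13 they were 5548 and 2, also 1 of 10.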
